A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

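The series holds 6 Agilent arrays with 2 colours, 3 for the ada2 deletion strain against wild type and 3 for the deletion strain with plasmid-borne ada2rlr against the same strain with plasmid-borne ADA2. Per the labels' protocols, total RNA was amplified to cRNA with a linear kit and coupled to Cy3 and Cy5 dyes by a service company. Spot signals and local backgrounds were deposited as intensity values of the Agilent Feature Extraction software, whose processed intensity is background-subtracted and dye-normalised, per the file headers. The log10 ratio in the scanner files is red over green processed signal, per the file headers. The value table that the authors deposited held log10 ratios equal to the scanner's within 1e-05 on 92.9 to 99.7% of spots. Its sign had been turned on the swapped arrays so that it reads mutant over control, and its column medians were -0.00104, -0.000199 and 0.0101 for the deletion and -0.0101, -0.00452 and -0.00354 for ada2rlr; no further centring was seen, and none is stated. The log2 ratios given here were computed from the deposited intensity values.

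Mean signals and median backgrounds of both channels were corrected with normexp (offset 50) over all spots and normalised by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3, with tables read by the data.table package (version 1.17.8). Each ratio was turned to mutant over control from the dyes in the labels. Control spots and spots marked as outliers by the scanner software (96, 334 and 710 gene spots on the deletion arrays, 2, 1 and 6 on the others) were left out, and the log2 ratios of the spots of a probe were averaged. Every gene had 1 probe, and the array type registered as tiling held no tiling probes, so the test of tiling probes and the choices among probes of a gene that had been planned were not run. A probe entered when it was well above background in at least 1 channel on each array of its comparison, by a share of at least 0.5 of its spots, which left 6159 genes in the deletion comparison and 5791 in the other, with 97 and 465 left out. Of the 6256 systematic names 5756 were found in the table of assembly R64. Gene symbols are those of that table where it gave one and those of the files otherwise. No coordinates were used.

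Each comparison was tested with lmFit and eBayes of limma on its 3 arrays against a log2 ratio of 0, two-sided, with Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. A ratio within an array is the paired difference of a mutant and a control RNA. The unequal number of arrays in each dye orientation leaves part of a gene-specific dye effect in each mean. The difference between the effects was tested with limma on the 6 arrays over the 5717 genes in both, and shared calls with Fisher's exact test. Lists of genes were tested with camera (inter-gene correlation 0.01), also with an estimated correlation, and with fry, which asks whether the genes of a list move, on balance, one way and makes no comparison with other genes. With an estimated correlation no list passed in either comparison, although in simulated data that test passed 0 of 8 shifted lists too. The simulated genes were drawn independently, so the simulation does not test camera where genes of a list move together. In the data the estimated correlations ran from -0.0843 (hexose transporters) to 0.933 (glycolysis) in the deletion. In ada2rlr they ran from -0.106 (DNA damage) to 0.937 (PAU genes). The tests, the alternatives, the rule for named genes and 36 lists taken from general knowledge of yeast were fixed before the data were examined. A list of subtelomeric genes needed coordinates and was replaced by the 8 outermost reading frames of each arm, before its result was seen, and the group of mitochondrially encoded genes and the list test of the difference were added after the data were seen. Members were matched by symbol, so that MLP1 in the cell wall list is the nuclear pore gene of that name. Lists with fewer than 3 measured members were not tested, which left 35 and 34.

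Genes were named by rule: ADA2, the 10 largest changes each way among genes called and alike in sign on 3 of 3 arrays, the 3 members with the largest change in each list that passed, the called members of the SAGA list, and PHO5, PHO84, HIS3, INO1, GAL1, ADH2 and HSP12. For the difference the 10 genes with the smallest p were named. URA3 was named as the plasmid marker, and HIS3, LEU2, MET17 and URA3 are altered in the strain background. For CHA1, CTT1, FMP48 and PHO84 the values of the other comparison were given beside the named one. Not every gene named by rule is given with its value.

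The steps were tested on simulated data with the spread of the real arrays, in which 200 genes were changed. The simulated arrays were independent, without the shared slide and dye orientation of the real ones. The false calls below therefore do not cover errors from slide or dye. In the deletion comparison (6159 genes) 38.8, 70.1 and 93.9% of genes changed by 0.5, 1 and 2 on the log2 scale were called, with 2 of 137 calls false. In the ada2rlr comparison (5791 genes) the shares were 50.7, 85.1 and 100%, with 6 of 163 false, and for the difference (5717 genes) 35.8, 82.1 and 98.5%, with 8 of 152 false. Of 8 lists shifted by 0.3, 8 passed camera in each comparison, with 1 and 0 other lists, among genes drawn without correlation.

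Alternatives were no background correction, plain subtraction, the processed signals, median centring, Aquantile after loess, the deposited value table, other filters on dim and saturated probes, a dye term, trended and robust eBayes, medians over spots, a stricter threshold, a replicate block for the difference, scaling each comparison by its spread, and leaving out each array. The slide as a random block could not be fitted to 3 arrays on 2 slides, and averaging the arrays of a slide took its place. Figures were drawn with matplotlib 3.10.9.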

Results

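RNA levels of Saccharomyces cerevisiae were measured on 6 arrays with 2 colours, each of which set a mutant strain against its control in the same hybridisation. On 3 arrays a strain lacking ADA2 was compared with wild type. On 3 others the deletion strain carrying the ada2rlr allele on a plasmid was compared with the same strain carrying wild-type ADA2 on that plasmid. Ada2 is a subunit of the SAGA and ADA coactivator complexes, in which it works with the histone acetyltransferase Gcn5. The series asks what the central region of Ada2 contributes to gene regulation, and the labels do not list the residues that the rlr allele changes. Both array types carried the same 6256 probes, 1 for each open reading frame. A probe had a median of 2 spots in the deletion comparison and 7 in the ada2rlr comparison. Between 99.5 and 99.7% of gene spots were well above background on the deletion arrays, against 91.1 to 93.5% on the ada2rlr arrays, and the number of arrays limits the precision of every value below.

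In each comparison the mutant RNA carried Cy5 on 2 arrays and Cy3 on 1. Across genes, which are not independent replicates, the log2 ratios of the deletion arrays correlated at r = 0.93 within one dye orientation. They correlated at 0.61 and 0.62 with the array of swapped dyes, which also lay on another slide scanned at another time, so dye and slide cannot be told apart there. The ada2rlr arrays shared 1 slide and correlated at r = 0.61 within one orientation and at 0.39 and 0.65 with the swapped array.

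The ADA2 transcript (YDR448W) was lower in the deletion strain on 3 of 3 arrays, with a mean log2 change of -2.49 ± 0.12 (SD, n = 3; limma adjusted p = 0.000564). Its probe still read well above background in the deletion channel on 3 of 3 arrays, and the place of the probe within the gene was not analysed here. In the ada2rlr comparison both strains carried the gene on a plasmid, and ADA2 changed by -1.24, 0.01 and -1.07 on the 3 arrays, a mean of -0.77 ± 0.68 (SD) that missed the threshold (limma adjusted p = 0.0557). The value near 0 came from array 2, which had the swapped dyes, and without it ADA2 stood at -1.16 (limma adjusted p = 4.43e-05). Without array 3, ADA2 stood at -0.62 (limma adjusted p = 0.00716), which does not show agreement: the values left were -1.24 and 0.01, and in that fit limma gave every gene the same spread. URA3, the uracil synthesis gene that marks the plasmid, was lower in the ada2rlr strain on 3 of 3 arrays (mean -1.06 ± 0.28, SD, n = 3; limma adjusted p = 0.00112). In the deletion comparison URA3 is altered in the background of both strains and was dim there, so that this comparison gives no contrast for it. The amount of plasmid-borne ADA2 was therefore not shown to be equal in the pair of plasmid strains.

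Among the 10 largest falls in the strain without ADA2 were acid phosphatase genes and mating genes, and among the 10 largest rises were CTT1, ARG1, ARG3, HSP12 and HSP26. SPL2 (YHR136C), which encodes a regulator of phosphate transport, had the largest fall, at -4.25 ± 0.04 (SD, n = 3; limma adjusted p = 0.000117). The acid phosphatase genes PHO11, PHO12, PHO3 and PHO5 followed with mean log2 changes of -3.14, -3.08, -2.67 and -2.52, and PHM6, a phosphate-responsive gene, with -2.60 ± 0.04 (SD). PHO11 and PHO12 are near-identical, and PHO3 resembles PHO5, so their probes may not separate them. Among mating genes, MFA1, a gene for a-factor, changed by -2.37 ± 0.25, BAR1, which encodes the protease that degrades alpha-factor, by -2.32 ± 0.09, and the pheromone-induced PRM6 by -2.16 ± 0.95 (SD, n = 3). CTT1 (YGR088W), the cytosolic catalase gene, had the largest measured rise, of 2.89 ± 0.20 (SD, n = 3, limma adjusted p = 0.000564), although that of HSP26, below, is not fixed. ARG1 and ARG3, of arginine synthesis, rose by 2.85 ± 0.05 and 2.80 ± 0.38. FMP48, which encodes a mitochondrial protein, rose by 2.63 ± 0.11, and the small heat shock gene HSP12 rose by 2.25 ± 0.21. HSP26, another small heat shock gene, was saturated in the mutant channel on 2 of 3 arrays, so that the size of its rise is not fixed. It was 2.16 here and 2.03 to 2.39 under the alternatives. ECM13 rose by 2.19, YBR116C by 2.09, CHA1, which encodes a serine and threonine deaminase, by 1.98, and the kinase gene RCK1 by 1.93. YBR116C is a dubious reading frame that overlaps TKL2. The change of SPL2, PHM6, BAR1 and ARG1 was alike on the 3 arrays. PHO5 fell less on the swapped array (-2.92, -2.89 and -1.74) and PRM6 fell more there (-1.64, -1.57 and -3.26). Under the alternatives the change of PRM6 ran from -3.39 to -1.61, so its size is not fixed.

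By limma, 931 of 6159 genes tested changed in the deletion strain at an adjusted p under 0.05, 433 of them higher and 498 lower. Of these, 114 changed at least 2-fold, 49 higher and 65 lower. The count of 931 rested on the arrays that entered: it was 362 without array 1, 145 without array 2 and 3317 without array 3, the last from the pair of arrays that shared a slide and a dye orientation. The test treats the 3 arrays as independent although 2 shared a slide. With the arrays of 1 slide averaged first 209 genes passed, while a dye term gave 3731. Of the 47 named genes that were called, 17, TAF9 and TAF10 among them, lost their call with the slide average.

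**Figure D1:**
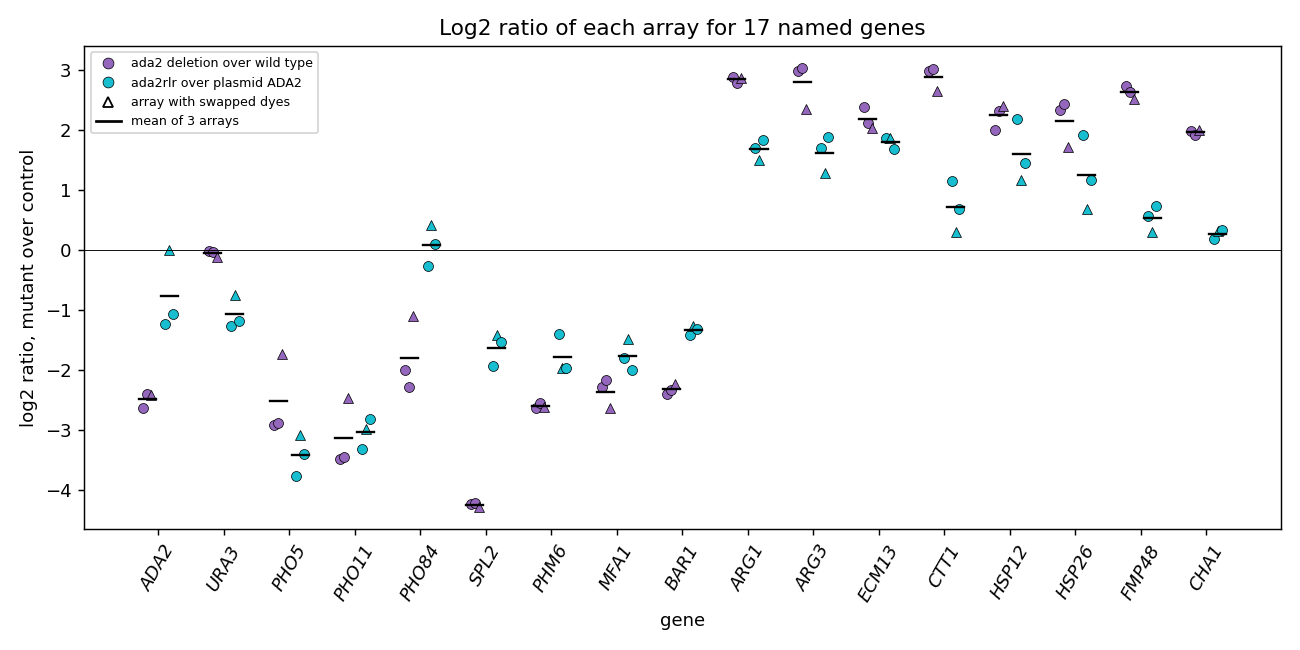
Log2 ratio of mutant over control (y axis) for 17 named genes (x axis), with 1 point per array, triangles for the array with swapped dyes and bars for the mean of 3 arrays. SPL2 lies near -4.25 on the deletion arrays and PHO84 near 0 on the ada2rlr arrays, while ADA2 is near 0 on the swapped ada2rlr array alone.

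Phosphate starvation genes, the targets of Pho4, fell as a group in the deletion strain: 16 of 16 passed over all genes, and 16 adjusted over the list alone. Their median log2 change was -1.59, and PHO84, the high-affinity phosphate transporter gene, changed by -1.80 ± 0.61 (SD, n = 3; limma adjusted p = 0.0143). Of 30 a-mating and pheromone genes, 26 fell and 4 did not pass, with 28 lower adjusted over the list alone and a median of -0.82. Of 18 purine biosynthesis genes 7 fell, among them MTD1 (-1.28), ADE17 (-1.09) and ADE13 (-1.01), with 11 lower adjusted over the list alone and a median of -0.59. The median of the purine list was -0.67 and -0.62 on arrays 1 and 2 but -0.14 on the swapped array 3. Genes of the iron regulon under Aft1 fell in 6 cases and rose in 1 of 26, with ENB1, a transporter gene for iron-bound enterobactin, at -1.55 ± 0.34 (SD), and 8 lower and 2 higher adjusted over the list alone. TIS11 (-0.72) and FRE1 (-0.68) lost their calls without array 2 (limma adjusted p = 0.0968 and 0.0958). The list of the unfolded protein response had 3 of 12 genes lower, 4 adjusted over the list alone. Its largest falls, PDI1 (-0.49) and HAC1 (-0.39), did not pass (limma adjusted p = 0.166 and 0.0715). SIL1 (-0.39) lost its call without array 1 or 2 (limma adjusted p = 0.219 and 0.201). By camera these 5 lists lay below the other genes, with adjusted p of 7.16e-19 for mating, 4.78e-13 for phosphate, 8.16e-06 for purine, 0.00302 for the unfolded protein response and 0.0227 for iron. With an estimated correlation none of them passed (adjusted p = 0.434 for mating, 0.601 for phosphate, purine and iron, and 0.72 for the unfolded protein response). The iron list did not pass without array 1 (adjusted p = 0.06) or array 2 (0.0794), nor the unfolded protein response without array 1 (0.0763).

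General stress genes, the targets of Msn2 and Msn4, rose in 20 cases and fell in 2 of 39, with 28 higher and 4 lower adjusted over the list alone and a median of 0.47. CTT1 and HSP12 belong to this list, as does HSP26, whose place in it is not fixed because of its saturated signal. Of 23 heat shock chaperone genes 10 rose, 11 adjusted over the list alone, with 1 lower adjusted over the list alone and a median of 0.46. Amino acid biosynthesis genes under Gcn4 rose in 18 cases and fell in 4 of 48, with 22 higher and 5 lower adjusted over the list alone and a median of 0.35. The median of this list was 0.19 and 0.17 on arrays 1 and 2 and 0.70 on the swapped array 3. Without array 3 its mean fell from 0.35 to 0.23 (camera adjusted p = 0.0109). ARG56, which encodes 2 enzymes of arginine synthesis, rose by 1.53 ± 0.17 (SD, n = 3; limma adjusted p = 0.00279). Of 25 sulfur and methionine genes 12 rose and 1 fell, with 15 higher and 1 lower adjusted over the list alone and a median of 0.37. MET6, the methionine synthase gene, rose by 1.68 ± 0.68 (SD), and SAM3, a transporter gene for S-adenosylmethionine, by 1.44 ± 0.31 (SD). STR3, of the same list, rose by 1.53 and lost its call without array 2 (limma adjusted p = 0.0882). Genes of the TCA cycle and respiratory chain rose in 10 cases and fell in 3 of 43, with 15 higher and 4 lower adjusted over the list alone. Among these, aconitase ACO1 rose by 1.12 and the ATP synthase genes ATP2 and ATP1 by 0.99 and 0.81. The median of the TCA list was 0.27 and 0.29 on arrays 1 and 2 but 0.05 on the swapped array 3. Of 72 ribosome biogenesis genes 10 rose and 62 did not pass, with 9 higher adjusted over the list alone and a median of 0.15. Histone genes rose in 3 of 11 cases, 5 adjusted over the list alone, and thiamine and vitamin B6 genes rose in 5 and fell in 1 of 19, with 7 higher and 1 lower adjusted over the list alone. By camera these 8 lists lay above the other genes, with adjusted p of 2.64e-10 for stress, 8.16e-06 for heat shock and ribosome biogenesis, 6.33e-05 for Gcn4, 0.000175 for sulfur, 0.0011 for the TCA cycle, 0.0217 for histones and 0.045 for thiamine. With an estimated correlation none of them passed (adjusted p = 0.434 for stress, ribosome biogenesis and the TCA cycle, 0.601 for heat shock, sulfur, histones and thiamine, and 0.711 for Gcn4). Histones did not pass without array 1 (adjusted p = 0.0581) or array 2 (0.0501), nor thiamine without array 1 (0.168), array 2 (0.105) or array 3 (0.0502).

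SAGA and ADA subunit genes, a list that holds ADA2 itself, did not shift against the other genes in the deletion strain by camera (adjusted p = 0.733). The list passed by fry, which makes no such comparison (adjusted p = 0.013). That result includes the deleted gene, at -2.49, and the list was not tested without ADA2. It therefore shows no shift of the other subunit genes. Of 20 measured, ADA2, TAF10 (-0.61 ± 0.28) and TAF9 (-0.47 ± 0.15, SD) fell and SPT7 (0.37 ± 0.12, SD) rose, with 4 lower and 2 higher adjusted over the list alone. The calls of TAF10, TAF9 and SPT7 were lost without array 1 (limma adjusted p = 0.0735, 0.17 and 0.215) or without array 2 (0.172, 0.201 and 0.302). The median of this list was 0.04 and its mean -0.13, with the test pointing down. INO1, ADH2 and GAL1, of inositol synthesis, ethanol use and galactose use, did not pass in the deletion strain, with changes of -0.02, 0.09 and 0.21 (limma adjusted p = 0.823, 0.406 and 0.108). HIS3 was not well above background and had no test.

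Of 35 lists tested in the deletion comparison, 22 did not pass by camera (adjusted p = 0.061 to 0.852). These were SAGA and ADA subunits, galactose, glycolysis and fermentation, hexose transporters, glucose-repressed carbon genes, ribosomal proteins, inositol and phospholipid, ergosterol, alpha-cell, daughter-cell, cell wall, flocculation and adhesion, zinc, multidrug resistance, nitrogen catabolite, cell cycle G1 and S, cell cycle G2 and M, proteasome, DNA damage, sporulation, PAU and COS genes. Ribosomal protein genes rose in 4 and fell in 15 of 137 cases, and the same counts held adjusted over the list alone. The median of the glycolysis list was -0.28 and -0.27 on arrays 1 and 2 and 0.34 on the swapped array 3, and its median over the array means (-0.07) and its mean (0.17) differed in sign, with the test pointing up. Hexose transporter genes also had a median (0.17) and a mean (-0.09) of unlike sign, with the test pointing up. Leaving out 1 array let 7 of these lists pass camera: COS genes without array 1 (adjusted p = 0.0255), glycolysis without array 1 (0.0156), cell wall genes without array 1 (0.0255) or array 2 (0.0144), PAU genes without array 2 (0.0329), and glucose-repressed (0.0253), ergosterol (0.00644), ribosomal protein (0.0115) and PAU genes (0.00436) without array 3. PAU genes then pointed up without array 2 (mean 0.16) and down without array 3 (mean -0.17). With all arrays kept, a dye term let glycolysis (adjusted p = 0.0326), cell wall (0.0215), PAU (0.0215) and COS genes (0.0224) pass, and median centring the ribosomal proteins (0.00158), against highest values over the alternatives of 0.946, 0.795, 0.953, 0.72 and 0.966. GAL1 passed without array 3 (limma adjusted p = 0.00439) and also with a dye term and all arrays kept.

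Many of the phosphate and mating genes that were lower in the deletion were also lower in the ada2rlr strain than in its control, and ARG1, ARG3, HSP12 and HSP26 were higher. PHO5 (YBR093C), PHO11 and PHO12 fell most, with mean log2 changes of -3.42 ± 0.34, -3.04 ± 0.25 and -2.99 ± 0.45 (SD, n = 3; limma adjusted p = 2.13e-06, 2.13e-06 and 1.24e-05). FUS1, needed for cell fusion in mating, changed by -1.93 ± 0.14, MFA1 by -1.77 ± 0.26, PHM6 by -1.78 ± 0.32 and SPL2 by -1.63 ± 0.27 (SD, n = 3). AFB1 changed by -1.70 and PHO89, a phosphate transporter gene, by -1.38. OPT2, a peptide transporter gene, was lower, but its mutant channel was well above background on 1 of 3 arrays, so that the size of its fall is not fixed (-1.35 here, -2.91 to -0.97 under the alternatives). ECM13 (YBL043W) had the largest measured rise, of 1.81 ± 0.11 (SD, n = 3, limma adjusted p = 1.24e-05), although that of AI5_BETA, below, is not fixed. ARG1 and ARG3 rose by 1.69 ± 0.17 and 1.63 ± 0.31, and HSP12 and HSP26 by 1.61 ± 0.53 and 1.26 ± 0.62 (SD, n = 3), the call of HSP26 being lost under median centring (limma adjusted p = 0.0726, the highest of 1.05e-12 to 0.0726 over the alternatives). SGA1, a glucoamylase gene, rose by 1.12, RSB1, a lipid transport gene, by 0.98, PRY1, which encodes a sterol-binding protein, by 0.94, and VID24, which encodes a protein of vacuolar degradation, by 0.91. AI5_BETA, a mitochondrial intron reading frame, was higher, but its control channel was well above background on 1 of 3 arrays, so that the size of its rise is not fixed either (1.07 here, 0.76 to 2.47 under the alternatives). All of these changed the same way on 3 of 3 arrays.

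By limma, 434 of 5791 genes tested changed in the ada2rlr strain at an adjusted p under 0.05, 214 higher and 220 lower. Of these, 32 changed at least 2-fold, 7 higher and 25 lower. Median centring left 116 of the 434 calls (39.7% of them higher), and the processed signals gave 61 genes with a 2-fold change in place of 32. The count of 434 fell to 226 without array 3, and was 595 without array 1 and 434 without array 2. Without array 3 limma pooled the spread of all genes completely, so that those calls follow the size of the change alone.

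Phosphate starvation genes fell in 14 of 16 cases in the ada2rlr strain, 15 adjusted over the list alone, with a median of -1.04. PHO84 was an exception, at 0.08 ± 0.34 (SD, n = 3; limma adjusted p = 0.734). Of 28 a-mating and pheromone genes 19 fell, with 21 lower and 1 higher adjusted over the list alone and a median of -0.45, and BAR1 changed by -1.33 ± 0.07 (SD). Purine biosynthesis genes fell in 2 of 18 cases, 5 adjusted over the list alone, with IMD2, which encodes a dehydrogenase of GMP synthesis, at -0.64 ± 0.26 (SD). The median of the purine list was -0.06, -0.43 and -0.18 on arrays 1, 2 and 3. Ergosterol synthesis genes fell in 4 and rose in 1 of 26, with 9 lower and 1 higher adjusted over the list alone, and nitrogen catabolite genes fell in 6 and rose in 1 of 27, with 7 lower and 3 higher adjusted over the list alone. The ammonium permease gene MEP1 (-0.57) and UGA1 (-0.52), of GABA breakdown, led the nitrogen list, while ERG9 (-0.46), ERG7 (-0.44) and ERG4 (-0.37) led the ergosterol list and lost their calls without array 3 (limma adjusted p = 0.153, 0.132 and 0.399). Median centring also removed the calls of these 3 (limma adjusted p = 0.103, 0.164 and 0.414) and of IMD2, MEP1 and UGA1 (0.0726, 0.0809 and 0.0523), while the lowest values over the alternatives were 0.0106, 0.011 and 0.0286, and 0.00135, 0.00262 and 0.00344. The camera test also placed ribosomal protein, proteasome, sporulation and G1 and S genes lower, with few or no members called: 3 lower and 1 higher of 137, 0 of 33, 1 lower of 16 and 0 of 22. Adjusted over the list alone, these counts were 0, 0, 4 lower and 1 higher, and 0. Camera adjusted p was 4.79e-20 for phosphate, 1.06e-15 for mating, 0.000679 for purine and ergosterol, 0.00403 for the proteasome, 0.0133 for ribosomal proteins, 0.017 for nitrogen, 0.042 for sporulation and 0.0496 for G1 and S. With an estimated correlation none passed (adjusted p = 0.272 for phosphate and mating, 0.436 for purine, ergosterol, nitrogen and proteasome, 0.449 for ribosomal proteins and G1 and S, and 0.57 for sporulation). Under median centring the mean of the ribosomal protein list turned from -0.06 to 0.05. The G1 and S list passed under 1 of 7 alternatives: it was lost under median centring (adjusted p = 0.102), with the processed signals (0.0679) and with a dye term (0.138) too, with a range of 0.0329 to 0.449. The proteasome list was lost under median centring (adjusted p = 0.102), with a range of 0.00303 to 0.436. Without array 1 the nitrogen (adjusted p = 0.0659), ribosomal protein (0.135) and G1 and S (0.16) lists did not pass, without array 2 sporulation (0.195) did not, and without array 3 the proteasome (0.0943), sporulation (0.15) and G1 and S (0.236) did not.

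Genes of the TCA cycle and respiratory chain rose in 19 of 46 cases in the ada2rlr strain, 35 adjusted over the list alone, with a median of 0.32. ACO1 rose by 0.70 ± 0.22, ATP3, an ATP synthase gene, by 0.64 ± 0.20 and COX7, a cytochrome oxidase gene, by 0.64 ± 0.13 (SD, n = 3). Under median centring the calls of ACO1, ATP3 and COX7 were lost (limma adjusted p = 0.061, 0.0505 and 0.0726, the highest over the alternatives, with lowest values of 0.000641, 0.000648 and 0.00149). Amino acid biosynthesis genes rose in 11 and fell in 1 of 47 cases, with 14 higher and 3 lower adjusted over the list alone, and ARG56 rose by 0.87 ± 0.22 (SD). The median of the Gcn4 list was only 0.06, and -0.00534 on array 1, against a mean of 0.17. Glucose-repressed carbon genes rose in 4 of 21 cases, 6 higher and 2 lower adjusted over the list alone, with the lactate transporter gene JEN1 at 0.66 and the malate dehydrogenase gene MDH2 at 0.58. Multidrug resistance genes rose in 4 of 13 cases, 4 higher and 1 lower adjusted over the list alone, and cell wall genes rose in 4 and fell in 2 of 30, 7 higher and 3 lower adjusted over the list alone, with PIR3 at 0.87. Histone genes rose in 2 of 11 cases, 3 adjusted over the list alone, ribosome biogenesis genes in 1 of 74, 0 adjusted over the list alone, and PAU genes, a family of similar sequences, in 0 of 24 by either count. Glycolysis genes rose in 4 and fell in 1 of 17, with 5 higher and 1 lower adjusted over the list alone, but their median was 0.59 and 0.82 on arrays 1 and 3 and -0.17 on the swapped array 2. FBA1, SED1 and CCW12, of glycolysis and the cell wall, likewise changed sign on that array and did not pass, but passed without it (limma adjusted p = 3.89e-05, 4.72e-06 and 4.43e-05) and with a dye term and all arrays kept (0.00537, 0.000641 and 0.0157), against highest values over the alternatives of 0.438, 0.354 and 0.473. SED1 also passed with the processed signals. Camera adjusted p was 1.06e-15 for the TCA cycle, 0.00032 for ribosome biogenesis, 0.00133 for PAU genes, 0.0029 for glycolysis, 0.0111 for histones, 0.013 for Gcn4, 0.0164 for glucose-repressed genes, 0.042 for the cell wall and 0.0496 for multidrug resistance. With an estimated correlation none passed (adjusted p = 0.272 for the TCA cycle, 0.436 for histones, glucose-repressed, cell wall and multidrug genes, 0.482 for ribosome biogenesis, 0.57 for Gcn4 and glycolysis, and 0.685 for PAU genes). Without array 1 the histone (adjusted p = 0.0692), glucose-repressed (0.0547) and multidrug (0.321) lists did not pass, without array 2 the PAU list (0.247) did not, and without array 3 glycolysis (0.0523) did not. The cell wall list was also lost with the processed signals (adjusted p = 0.058) and under median centring (0.0519), with a range of 0.0114 to 0.436 over the alternatives. The multidrug list was lost with the processed signals (adjusted p = 0.0679) and a dye term (0.0627), with a range of 0.0333 to 0.436, and the glucose-repressed list under median centring (0.162), with a range of 0.0144 to 0.436. The count of 18 lists in ada2rlr became 13 under median centring, 15 with the processed signals and 16 with a dye term.

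The other 16 of 34 lists tested did not pass in the ada2rlr comparison by camera (adjusted p = 0.0707 to 0.756). General stress genes were among them, with 8 higher and 4 lower of 39, 10 higher and 5 lower adjusted over the list alone, a median of 0.05 and a camera adjusted p of 0.176. The stress list passed higher without array 2 (camera adjusted p = 0.0161) or array 3 (0.00357) and not without array 1 (0.978), so its place in ada2rlr rests on array 1. Without array 2, inositol and phospholipid (camera adjusted p = 0.0394) and COS genes (0.0211) passed lower. Heat shock chaperones had 1 higher and 2 lower of 24 and sulfur genes 3 higher and 3 lower of 24. SAGA and ADA subunit genes had 0 of 20 called, 1 higher and 2 lower adjusted over the list alone, with a median of 0.04, a mean of -0.0032 and a test pointing up. The iron list had a median of 0.03 and a mean of -0.07, with the test pointing down. INO1, GAL1 and ADH2 did not pass, at -0.09, 0.25 and -0.31 (limma adjusted p = 0.555, 0.123 and 0.0703).

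Across the 5717 genes measured in both comparisons, the changes correlated at r = 0.61 (Spearman 0.46), with a slope of 0.408 for ada2rlr on the deletion. Of 112 genes that changed at least 2-fold in the deletion, 107 had the same sign in ada2rlr, 79 were called the same way there, and 105 changed more in the deletion. The median ratio of the ada2rlr change to the deletion change over these 112 was 0.436. Among genes called in the deletion, the median ratio was 0.754 for 16 phosphate genes, 0.628 for 25 mating genes, 0.401 for 22 Gcn4 genes, 0.269 for 22 general stress genes, 0.193 for 13 sulfur genes and -0.01 for 10 heat shock genes. PHO5 fell more in ada2rlr (-3.42) than in the deletion (-2.52), a difference of 0.91 that did not pass (limma adjusted p = 0.163). Both lists of calls held 136 lower genes, against 18.4 for independent lists (odds ratio 24.7, Fisher's exact p = 5.62e-96), and 103 higher genes, against 15.6 (odds ratio 15.5, Fisher's exact p = 2.98e-63). Only 5 genes were called in opposite directions, and genes are not independent replicates in these tests. Phosphate, mating and purine lists passed camera lower in both comparisons, and TCA cycle, Gcn4, histone and ribosome biogenesis lists passed higher in both, 7 lists in all. With an estimated correlation 0 of the 7 passed in either comparison (adjusted p = 0.434 to 0.711 in the deletion and 0.272 to 0.57 in ada2rlr), and the histone list did not pass without array 1 in either comparison or without array 2 in the deletion.

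**Figure D2:**
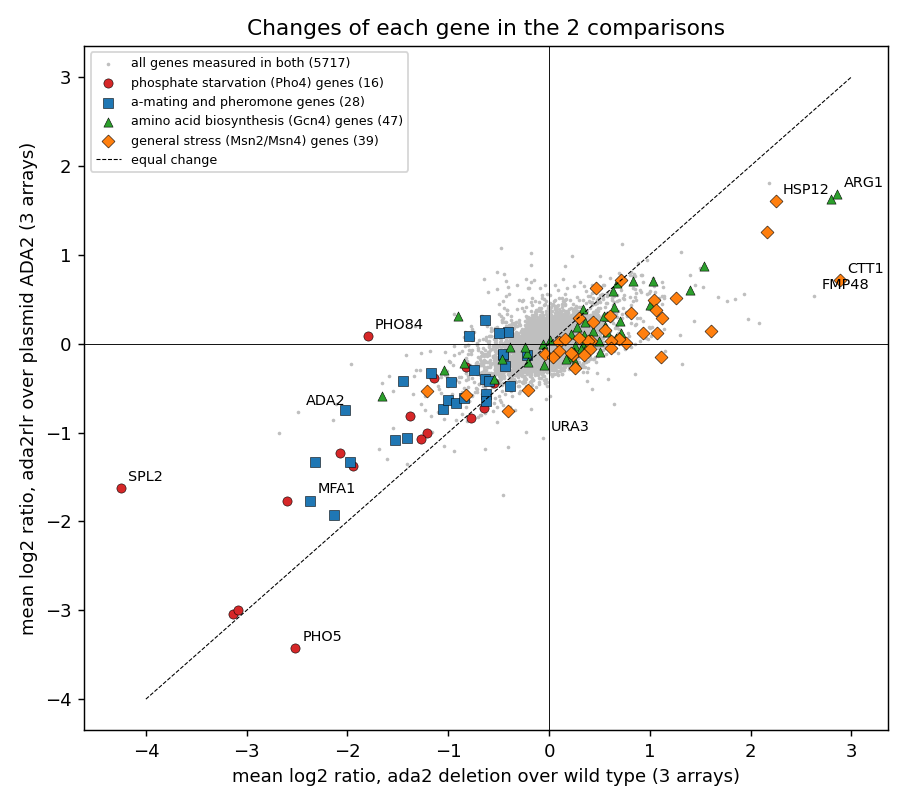
Mean log2 ratio of each of 5717 genes in the deletion comparison (x axis) and the ada2rlr comparison (y axis), 3 arrays each, with 4 lists of genes in colour and a dashed line of equal change. Of 16 phosphate genes 15 were below 0 in both comparisons, as were 24 of 28 mating genes, and 35 of 39 general stress genes, CTT1 among them, had a higher value in the deletion.

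The genes with the smallest p for a difference between the effects of the deletion and of ada2rlr were SPL2, CHA1, FMP48, AGA1 and PUT4. By limma on the 6 arrays, 194 of the 5717 genes differed at an adjusted p under 0.05, 78 with the deletion value above and 116 with it below. SPL2 differed by -2.62 ± 0.14 (SE, 3 arrays each; limma adjusted p = 0.000256), and PHO84 by -1.88 (limma adjusted p = 0.017), from -1.80 in the deletion to 0.08 in ada2rlr. FMP48 and CTT1 rose by 2.63 and 2.89 in the deletion and by 0.54 and 0.72 in ada2rlr, differences of 2.10 and 2.17 (limma adjusted p = 0.000343 and 0.00331). CHA1 rose by 1.98 in the deletion and was not called in ada2rlr (0.28), and PUT4, a proline permease gene, rose by 1.85 and 0.51, differences of 1.70 and 1.34 (limma adjusted p = 0.000256 and 0.00174). AGA1, of a-cell agglutination, fell more in the deletion (-2.03 against -0.74), as did YIL082W (-2.14 against -0.86), a reading frame of a repeated Ty element that was well above background in the ada2rlr channel on 1 of 3 arrays. For YIL082W the size of the difference is therefore not fixed, and it did not pass with the processed signals (limma adjusted p = 0.0925, the highest of 0.000429 to 0.0925 over the alternatives). CIT2, the peroxisomal citrate synthase gene, rose by 1.32 in the deletion and lay at -0.22 in ada2rlr, of opposite sign on every array (limma adjusted p = 0.00363). PHM7, a phosphate-responsive gene, differed by 1.24 and ARG1 by 1.17 (limma adjusted p = 0.00271 and 0.00378). Array type, plasmid and date differed between the comparisons too, so none of these differences can be assigned to the allele alone. The count of 194 was 56, 70 or 343 without deletion array 1, 2 or 3 and 52, 86 or 26 without ada2rlr array 1, 2 or 3, and 93 with each comparison scaled by its spread.

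**Figure D3:**
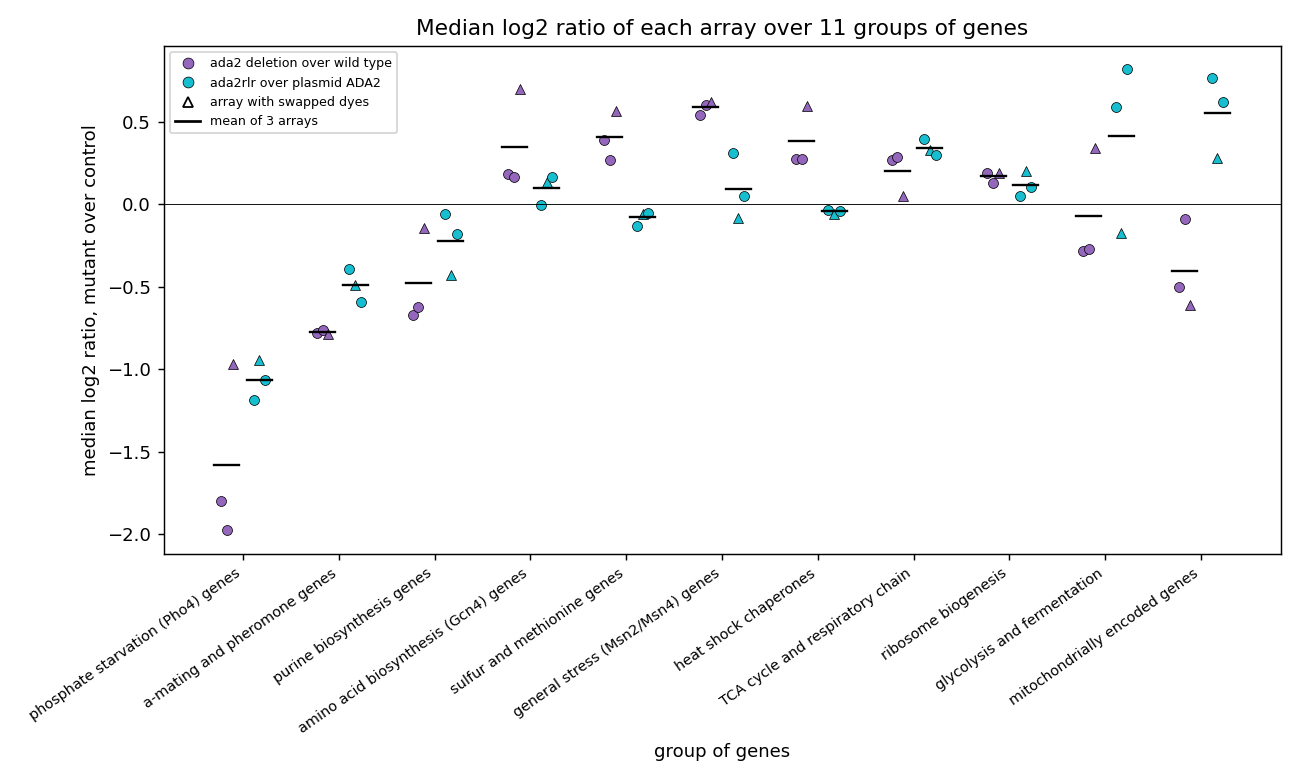
Median log2 ratio of mutant over control (y axis) for 11 groups of genes (x axis), with 1 point per array, triangles for the array with swapped dyes and bars for the mean of 3 arrays. The glycolysis median changes sign on the swapped array in both comparisons (0.34 and -0.17), while the mating median does not.

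Other groups of genes were formed after the files were read. The outermost genes of each chromosome arm rose in 30 and fell in 27 of 263 cases in the deletion, and rose in 11 and fell in 14 of 209 in ada2rlr, without a shift by camera (adjusted p = 0.852 and 0.547). Adjusted over the list alone the counts were 44 and 32, and 13 and 16. The medians of these outermost genes (0.01 and 0.06) and their means (-0.04 and -0.02) differed in sign, with both tests pointing up. Transcripts encoded in the mitochondrial genome fell in 1 of 23 cases in the deletion, 5 adjusted over the list alone, with a median of -0.39 (camera adjusted p = 0.0019; adjusted p = 0.711 with an estimated correlation). They rose in 10 of 13 cases in ada2rlr, 12 adjusted over the list alone, with a median of 0.61 (camera adjusted p = 1.33e-10; adjusted p = 0.417 with an estimated correlation).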

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

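The test of the difference for single genes was planned, while the list test of the difference and the tests below on URA3, ADA2, the plasmid, a single shrinking factor, the dyes and the spread of the RNA samples for mitochondrial transcripts were chosen after the results were seen.

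Named genes and lists are given here because the change in the deletion strain differed from that in the ada2rlr strain in a test of the difference itself, over 3 arrays each. By limma, 30 named genes passed (adjusted p = 0.000256 to 0.0393). The 10 genes named for the smallest p in this same test are among them by rule. Many of the others were named for a large change in 1 of the 2 comparisons, which favours a difference. The count of 30 is therefore no separate support, and over all genes 194 of 5717 passed. The value is the log2 change in the deletion minus that in ada2rlr. Genes with the deletion value below were SPL2 (-2.62), PHO84 (-1.88), ADA2 (-1.72), PHO3 (-1.67) and PHM6 (-0.83), the mating genes AGA1 (-1.28) and BAR1 (-0.99), YIL082W (-1.29), AI5_BETA (-1.55), COX7 (-1.04), TAF10 (-0.81), PIR3 (-0.71) and JEN1 (-0.71). Genes with the deletion value above were CTT1 (2.17), FMP48 (2.10), YBR116C (1.85), CHA1 (1.70), CIT2 (1.54), RCK1 (1.37), PUT4 (1.34), POT1 (1.29), AFB1 (1.25), PHM7 (1.24), SAM3 (1.18), ARG3 (1.17), ARG1 (1.17), URA3 (1.01), HSP104 (0.86), GRE2 (0.62) and ATP2 (0.60). The sizes for YIL082W and AI5_BETA are not fixed, since 1 ada2rlr channel of each was mostly not above background. URA3 shows no difference in effect, since both strains of the deletion comparison carry it altered and without the plasmid. The difference for ADA2 follows from the strains, since the deletion strain lacks the gene and both plasmid strains carry it. By camera, 12 groups differed, and none did with an estimated correlation (adjusted p = 0.111 to 0.717). The median difference was negative for mating (-0.36), phosphate (-0.38), flocculation (-0.28), purine (-0.23), iron (-0.18) and mitochondrially encoded genes (-1.13). It was positive for general stress (0.40), sulfur (0.45), heat shock (0.43), Gcn4 (0.26), DNA damage (0.21) and proteasome genes (0.13).

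ADA2 and URA3, both carried by the plasmid, read lower in the ada2rlr strain, ADA2 on 2 of 3 arrays. Dye bias of the URA3 probe is argued against by a mutant effect of -0.98 ± 0.10 (SE, largely pooled over genes) in the model with a dye term and by -0.74 on the swapped array. Dye bias of the ADA2 probe stays open, because 1 array alone carried the swapped dyes: the dye effect of this probe was -0.58 on the ada2rlr arrays and -0.0467 on the deletion arrays. Fewer copies of the plasmid may lower both genes alike, and ADA2 minus URA3 was 0.02 and 0.10 on arrays 1 and 3 but 0.75 on array 2, so this stays open too. An effect of the allele on both genes was not tested apart from these, and the falls in PHO5 and MFA1 cannot be assigned to altered Ada2 rather than less Ada2 from these arrays.

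Changes of the deletion strain were smaller in ada2rlr, with a median ratio of 0.436 over 112 genes. Compression by background signal as the whole cause is argued against by a median ratio of 0.469 in the 37 brightest genes. The ratio was 0.383 in the 38 dimmest and 0.441 in the 37 between. This rise with signal leaves a part played by background open. One factor for all genes is argued against by the ratios of phosphate and general stress genes, 0.754 and 0.269 (permutation p = 0.00046, two-sided, with genes that are not independent). Permuting genes leaves out the spread between arrays: the stress median in ada2rlr was 0.31, -0.08 and 0.05 on arrays 1, 2 and 3. The lists also differed in size in the deletion (medians -1.59 and 0.47), which the test does not allow for. Selection of genes for their size in the deletion may contribute: among 32 genes changed at least 2-fold in ada2rlr the deletion changed 23 more, with a median ratio of 1.22 and quartiles of 0.874 and 1.47, which leaves this open. A partial loss of function in ada2rlr remains a hypothesis beside this selection and beside array type.

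Mitochondrially encoded transcripts read lower in the deletion (median per array -0.50, -0.09 and -0.61) and higher in ada2rlr (0.77, 0.28 and 0.62) over 13 genes. Dye bias as the whole cause is argued against by the swapped arrays, which kept the sign of their comparison (-0.61 and 0.28). Over the 11 genes well above background in both channels on every array the median in ada2rlr was 0.61, the same as over 13. Leaving out so few could hardly move the median, so this shows only that the rise was present in probes above background. Of 23 mitochondrially encoded genes 13 were measured in ada2rlr, and the check does not cover those already filtered out. A part played by dim probes therefore stays open. Variation between RNA samples that moves the whole group together could remain, since an exact permutation test of 3 against 3 array medians gave p = 0.10, the smallest it can give. An effect of ADA2 on these transcripts was not tested apart from it.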

How the results depend on the processing

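The tests on the slide average and on shared calls without the swapped arrays were chosen after the data were seen, and the others were planned. Of the named genes, 33 of 54 in the deletion, 36 of 71 in ada2rlr and 8 of 10 for the difference kept direction and side of the threshold under every alternative run. For the difference the exceptions were ARG1 with scaling by spread (limma adjusted p = 0.138) and YIL082W with the processed signals (0.0925). Of the named genes that were called, 30 of 47 in the deletion and 34 of 49 in ada2rlr kept their call whichever 1 array was left out. The correlation between the comparisons stayed between 0.565 and 0.612.

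Genes called in the deletion (931) became 3731 with a dye term, 209 with the arrays of 1 slide averaged first and 170 at an adjusted p under 0.01. Without array 1, 2 or 3 they were 362, 145 and 3317, so between 145 and 3317. Other settings gave 741 to 1018. With array 3 out, the remaining arrays shared slide and dye, so that their agreement includes both, and 931 of the 931 calls were kept. Genes called in ada2rlr (434) became 116 under median centring, 166 at an adjusted p under 0.01 and 226 to 595 with 1 array left out. Their 2-fold count (32) became 61 with the processed signals and 61 with the deposited value table. Median centring also moved the share of higher calls from 49.3 to 39.7%. The cause was not tested. Fits of 2 arrays and those with a dye term have 1 residual degree of freedom per gene, so the spread is mostly pooled over genes: a gene's own spread had a weight of 7.15% with a dye term and 7.77% without array 3 in the deletion, and 0 without array 3 in ada2rlr, against 40.0 and 22.7% with all arrays.

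ADA2 in ada2rlr (-0.77, not called) passed with a dye term (-0.58), with trended eBayes (-0.77) and without array 2 or 3 (the values left without array 3 do not agree), ranging from -1.16 to -0.53 with 1 array left out. PHO84 in ada2rlr (0.08) reversed to -0.0849 without array 2 (up to 0.25 with another left out). The PAU list in the deletion reversed to a mean of -0.17 without array 3 (up to 0.16 with another left out), and the ribosomal protein list in ada2rlr to 0.0545 under median centring. With an estimated correlation 0 of 13 and 0 of 18 list calls held, and by fry 9 lists passed in the deletion, 5 of them among the 13, and 2 in ada2rlr, both among the 18. With median centring, processed signals and a dye term 12, 13 and 15 lists passed camera in the deletion and 13, 15 and 16 in ada2rlr. In the deletion, median centring lost histones (adjusted p = 0.134) and thiamine (0.0635), and a dye term lost iron (0.0641) and thiamine (0.112), while 1 list gained a call with median centring and 4 with a dye term. Over the alternatives the adjusted p ran from 0.00644 to 0.601 for histones, 0.0309 to 0.601 for thiamine and 0.00124 to 0.601 for iron. The cause was not tested. With 1 array left out, 9 of 13 lists in the deletion and 8 of 18 in ada2rlr always passed.

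The difference (194 genes) became 93 with each comparison scaled by its spread and 26 to 343 with 1 array left out, where the remaining arrays of both comparisons share one spread. With a replicate block it became 308, of which 191 were among the 194. Same-numbered arrays shared only a number: their deviations correlated at 0.386, -0.439 and 0.297, and not every array correlated best with its own number. Shared calls (239) became 66 at an adjusted p under 0.01, 25 with at least a 2-fold change and 443 with a dye term (85.2 lower and 96.6 higher for independent lists), and 326 without the swapped array of each comparison.

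Aquantile moved nothing, since it leaves ratios within arrays unchanged, and medians over spots moved nothing in the deletion, where a probe had a median of 2 spots. The slide as a random block could not be fitted, and the alternatives on tiling probes, strand and 3 prime probes were not run. The filter against background left out more probes in ada2rlr, 465 against 97. Median signals were higher on those arrays, but so were the medians of their negative controls, at 273 to 567 against 62.0 to 97.6 on the deletion arrays.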

Other observations

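Turning the sign of 1 array in each comparison was planned as a check. The 4 sign patterns of 3 arrays are too few for a share under 0.05. In the deletion the real pattern called 931 genes and the highest other 0 by limma (2078 and 323 at an unadjusted p under 0.05), so 1 of the 4 reached the real count. In ada2rlr the real pattern called 434 genes and the highest other 0 by limma (1433 and 186 at an unadjusted p under 0.05), again 1 of the 4. By camera the deletion had 13 lists and the highest other 15, so 2 of the 4 reached 13. The pattern with 15 turned array 3, which follows slide and dye, and within the other slide 16 lists passed. In ada2rlr 18 lists passed and the highest other had 14, 1 of the 4. For the difference, 1 of the 10 splits of the 6 arrays reached 194 genes, and the highest other called 0 by limma. At an unadjusted p under 0.05 the real split had 1145 genes and the split of deletion arrays 1 and 2 with ada2rlr array 1 had 1184, so 2 of the 10 reached the real count on that measure. The 10 splits are again too few for a share under 0.05.

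In all, 342 of 5717 genes had opposite signs in the comparisons on every array, fewer than the 750 of unrelated comparisons with the same shares of genes alike in sign (57.9% in the deletion and 45.4% in ada2rlr), and 66 of the 342 passed the test of the difference. The deviations of the 2 swapped arrays from the means of their comparisons correlated at r = 0.33 across genes. With 1 swapped array each, these deviations are the estimated dye effects, and in the deletion they include the slide. A dye effect common to both comparisons would remain in both means and could add to their correlation and shared calls. The correlation of the comparisons stayed between 0.565 and 0.612 over the alternatives, a dye term among them.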
